A study of Caenorhabditis elegans with 13 samples.

How the data were processed

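Small RNA was sequenced from whole N2 worms in 13 libraries, 1 for each diet and adult day sampled. Per the labels' protocols, total RNA was precipitated with ethanol, RNA of 18 to 30 nt was selected on a 6% polyacrylamide gel, and adapter ligation and amplification followed an Illumina small RNA kit, version 1.5. No molecular identifiers are mentioned. The deposited values are raw read counts per mature miRNA and precursor, per the file headers, with 447 entries in each file and a different total in each library. The aligner, counter, miRNA database release, genome build and filters behind these counts are not given in the sources used here. Diet and day were taken from the labels, which also number the libraries; in all 3 diets the number stands for the day, so day is used here.

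Entries that list the same mature miRNA under several precursors were collapsed to the highest of their counts, which left 434 mature miRNAs and removed at most 0.219% of the reads of a library. Totals after that ranged from 2639586 to 5143918 reads. A floor of 3 reads corresponds to 0.583 to 1.137 CPM. Intervals of shares are 95% Wilson intervals. Both cover counting error only.

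Of 250 precursors, 247 were matched by name to the WBcel235 annotation of Ensembl release 115, and 3 were not, let-7 among them, so no position is given for these. Hairpins at most 10000 bp apart on a strand were grouped into 26 clusters of 2 or more. Coordinates are 1-based and come from that annotation. A hairpin is called intergenic where no protein-coding gene contains it, and other kinds of gene were not checked.

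Counts were analysed with edgeR 4.0.16 in R 4.3.3, with trimmed mean of M values (TMM) scaling (factors from 0.472 to 1.63) and a filter of 10 reads in 4 libraries. Diets were compared with edgeR's quasi-likelihood test in a model of diet and day as factors on the 12 libraries of days 4 to 10, all diets sharing 1 estimate of the spread. Age was tested on the 13 libraries with day as a number and diet as a factor, the slope of each diet in a model with separate slopes, and slopes that differ between diets by an F test on the 12 libraries. Tests of single miRNAs and of lists are two-sided. Permutation tests are one-sided: they count draws with as large a share or spread, or with neighbours or arms at least as close. p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and the SE is the log2 fold change divided by the square root of its F statistic. The 15 miRNA lists were families, mirtrons, miRNAs with lifespan phenotypes and tissue markers, each entry standing for the arm of its hairpin with more reads over all libraries. Lists with 3 or more tested members were tested with fry of limma 3.58.1, 13 in all, with adjustment over the lists of a comparison; tissue markers were left out of these because they do not form a group with 1 direction, and the lin-4 family had too few members. Of the 11 lifespan entries, 6 also stand in another list, as do the 3 of the mir-238 family; mir-62 stands in the mir-50 family and among the mirtrons. Shares of variance were computed on log2 CPM with a prior count of 2 and tested by exact permutation within days or within diets.

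The models, lists, naming rule and 126 alternatives were fixed before the data were examined, and 12 alternatives were added later. The rule named, for each comparison, the 10 miRNAs with the largest log2 fold change in each direction among those past the threshold. Where fewer than 10 passed, those with the smallest p were added up to 10 and given as values. Every tested list member and the 10 miRNAs of highest mean CPM could also be named. An arm with a mean CPM under 10 is named only as low.

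Day was kept as a block because the libraries of a day share that label and moved together. After removing diet means, all 12 libraries had their highest correlation with a library of another diet on their own day. The correlation was 0.557 to 0.896 (median 0.769) over the 12 pairs of the same day and -0.585 to 0.312 (median -0.269) over the 36 pairs of other days and diets.

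The alternatives were DESeq2 1.42.0, limma-voom, other scalings (DESeq2 size factors, total counts, total counts without the top 3 miRNAs), no low-count filter, a filter of 100 reads in 4 libraries, counts summed over precursors, an adjusted p threshold of 0.10, no day block, day as a number or as its logarithm, only the 2 diets compared, no diet term, limma-voom with day as a random block for age (correlation within days 0.679), camera with a preset correlation of 0.01 or an estimated one, and each library or day left out. Permutation tests of clusters, arms and random sets used 10000 draws. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and plots.

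The tests were run on simulated data of the same size in which 40 miRNAs were changed, 20 by each of 2 sizes. For the diet comparisons the sizes were 2-fold and 4-fold: 2 and 17 of 20 were recovered for CR against AL, 4 and 18 for IF against AL, and 4 and 20 for CR against IF. For slopes they were 4-fold and 16-fold over 6 days: 7 and 16 of 20 were recovered for age, 1 and 6 for the AL slope, and 0 and 0 for the CR slope, the IF slope and diet by age. Unchanged miRNAs called were 1 for CR against AL, 3 for IF against AL, 2 for the AL slope and 0 for the others. Simulated libraries were drawn independently of each other. For age and the slopes they therefore lack what real libraries of a day share beyond a linear trend. The recoveries and false calls given for these tests do not cover that.

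miRNA targets, isoforms and sequence composition were not analysed here. miR-44-3p and miR-45-3p were both kept, and miR-45-3p was left out in an alternative. In the mir-35, mir-51, mir-58 and other families with near-identical members, reads could have been split between members by a counting step that is not described.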

Results

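MicroRNAs (miRNAs) are small RNAs of about 22 nt that lower the output of target mRNAs. They were counted in 13 small RNA libraries from whole N2 worms, the standard laboratory strain of Caenorhabditis elegans. The animals were fed ad libitum (AL) or kept on 1 of 2 other regimens, which the labels abbreviate as CR and IF without describing either protocol. AL worms were sampled on adult days 2, 4, 6, 8 and 10, and CR and IF worms on days 4, 6, 8 and 10, with 1 library per diet and day. The series title places the work on dietary restriction and longevity, and the design is a time course of aging. The reads counted per library came to 3174231 to 5143918 in AL, 2882741 to 4000827 in CR and 2639586 to 4128030 in IF, spread over 434 mature miRNAs. Because no diet was sampled more than once on a given day, the errors below measure how far a difference varied between days. The labels do not say whether libraries came from separate cultures.

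A few miRNAs held most of the reads, and which ones they were changed with the day. miR-58a-3p, of the bantam-like mir-58 family that acts on growth signalling, made up 66.5% of the AL reads on day 4, 31.4% on day 6, 24.0% on day 8 and 48.5% on day 10. On the same 4 days it made up 47.5%, 20.7%, 10.4% and 37.9% in CR and 36.0%, 13.8%, 11.5% and 41.1% in IF. miR-48-5p, a let-7 family member of the larval timing pathway, rose to the top of all 3 day 8 libraries, with 33.3% in AL, 39.1% in CR and 26.4% in IF. In the other 10 libraries it held between 0.721% and 5.65%. miR-35-3p, of a family abundant in oocytes and embryos, led the IF library of day 6 with 15.8%, against 5.93% in AL and 11.4% in CR. The 95% Wilson intervals of these shares spanned at most 0.116 percentage points and cover counting error only, since reads amplified by PCR are not independent molecules. miR-44-3p and miR-45-3p carried the same reads: their counts were equal in 10 of 13 libraries and never differed by more than 1 read.

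**Figure D1:**
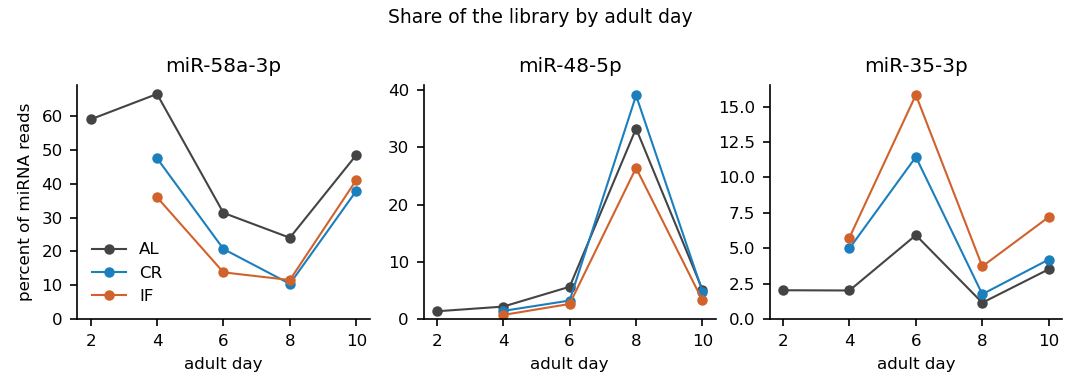
Percent of all miRNA reads (vertical axes, each from 0) held by miR-58a-3p, miR-48-5p and miR-35-3p on each adult day (horizontal axes); each point is 1 library and lines join the libraries of a diet. miR-48-5p reaches 26.4% to 39.1% on day 8 and stays at or below 5.65% on other days.

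Over the 12 libraries of days 4 to 10, day accounted for 74.9% of the variance of log2 CPM summed over 212 tested miRNAs, diet for 11.4% and the remainder for 13.7%. Exchanging diets within days gave a diet share of 6.27% on average, and the real share was the largest of the 216 arrangements (exact permutation p = 0.00463, the smallest possible). Exchanging days within diets gave a day share of 29.5% on average, and the real share was the largest of 576 (exact permutation p = 0.00174, the smallest possible). Without the day 8 libraries the diet share was 20.1%, but exchanging diets then gave 12.7% on average. The day share was 61.9%, against 26.65% on average with days exchanged. Each had exact permutation p = 0.0278, the smallest that 36 arrangements allow.

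The first comparison asked which miRNAs differ between IF and AL worms of the same age. In IF, miR-37-3p of the mir-35 family, miR-49-3p and a group of arms from 1 stretch of chromosome X rose, while miR-58a-3p, miR-48-5p, miR-77-3p and miR-70-3p fell. miR-37-3p averaged 7078 CPM (read counts scaled to a common library size) in AL (SD 2835, n = 4 days) and 32610 CPM in IF (SD 9880, n = 4 days), a log2 fold change of 2.25 ± 0.34 (SE; edgeR adjusted p = 0.00169). miR-58a-3p averaged 555800 CPM in AL (SD 311400, n = 4 days) and 227700 CPM in IF (SD 126800, n = 4 days), a log2 fold change of -1.32 ± 0.30 (edgeR adjusted p = 0.0105). In all, 31 of 212 tested miRNAs passed edgeR's quasi-likelihood test at an adjusted p under 0.05, 19 higher and 12 lower in IF. All 31 differed in the same direction on 4 of 4 days, which the test itself favours, as it weighs a difference against its variation between days. Among all 212, 72 differed in the same direction on 4 of 4 days, where 26.5 are expected by chance. That count was also above 26.5 where 0 miRNAs passed: 55 for CR against AL and 48 for CR against IF. For IF against AL, 66 miRNAs passed at an unadjusted p under 0.05, where 10.6 are expected with no difference. Scaling by total counts raised the median log2 fold change of all miRNAs by 0.458 and gave 42, split into 37 higher and 5 lower in place of 19 and 12; the mir-35, mir-50, mir-51 and mir-58 families kept their directions under each scaling tried.

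The miRNAs that rose most in IF were, besides miR-37-3p, miR-797-5p (log2 fold change 2.44 ± 0.54), miR-4810b-3p (2.32 ± 0.56), miR-2220-3p (2.25 ± 0.38), miR-4810a (2.24 ± 0.63), miR-4807 (2.21 ± 0.37), miR-4923b (2.16 ± 0.66) and miR-49-3p (2.12 ± 0.39). In AL over days 4 to 10, miR-797-5p (mean 5.19 CPM), miR-4810b-3p (5.96), miR-4810a (3.28) and miR-4923b (6.45) averaged under 10 CPM. Their fold changes thus rest on low AL counts. miR-2220-3p (14.47), miR-4807 (17.37) and miR-49-3p (526) averaged over 10 there. miR-4808-3p (2.72 ± 0.49) and miR-2208a-5p (2.10 ± 0.54) also rose but were low, with mean CPM over all libraries of 9.80 and 2.26. Of these, mir-4807, mir-4808, mir-2220, mir-4810b, mir-4810a and mir-4923b lie between positions 1872466 and 1879698 of chromosome X in the WBcel235 assembly, all intergenic and on the plus strand. The largest falls were those of miR-236-3p (-2.58 ± 0.67), miR-77-3p (-2.18 ± 0.36), miR-75-3p (-1.93 ± 0.40), miR-70-3p (-1.78 ± 0.44), miR-73-5p (-1.50 ± 0.47), miR-46-3p (-1.46 ± 0.32), miR-48-5p (-1.39 ± 0.31), miR-58a-3p and miR-82-3p (-1.26 ± 0.38). miR-70-5p (-2.54 ± 0.69) fell as well but was low, with a mean CPM of 2.26. miR-236-3p fell mostly on early days: its log2 ratio to AL was -4.20 on day 4 and -3.38 on day 6, against -0.61 on day 8 and -0.66 on day 10. The mir-58a hairpin lies in an intron of Y67D8A.2 (chromosome IV, 3233254 to 3233350), mir-82 in an intron of gid-2 (chromosome X, 2435258 to 2435354) and mir-70 in an intron of pmp-5 (chromosome V, 6665536 to 6665635).

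**Figure D2:**
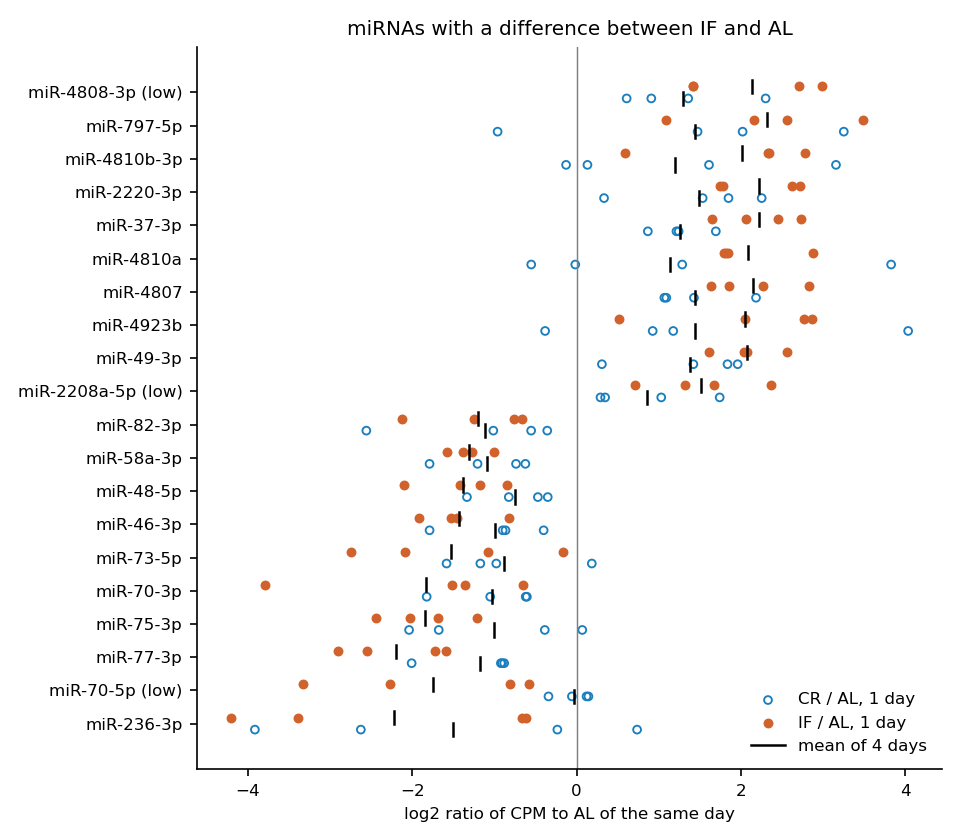
log2 ratio of CPM to the AL library of the same day (horizontal axis) for the 20 miRNAs with the largest fold changes among those that passed the IF against AL test (vertical axis); filled points are IF and open points CR, 1 per day, and black ticks are means of 4 days. All IF points of the upper 10 miRNAs lie above 0 and all those of the lower 10 below 0.

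**Figure D3:**
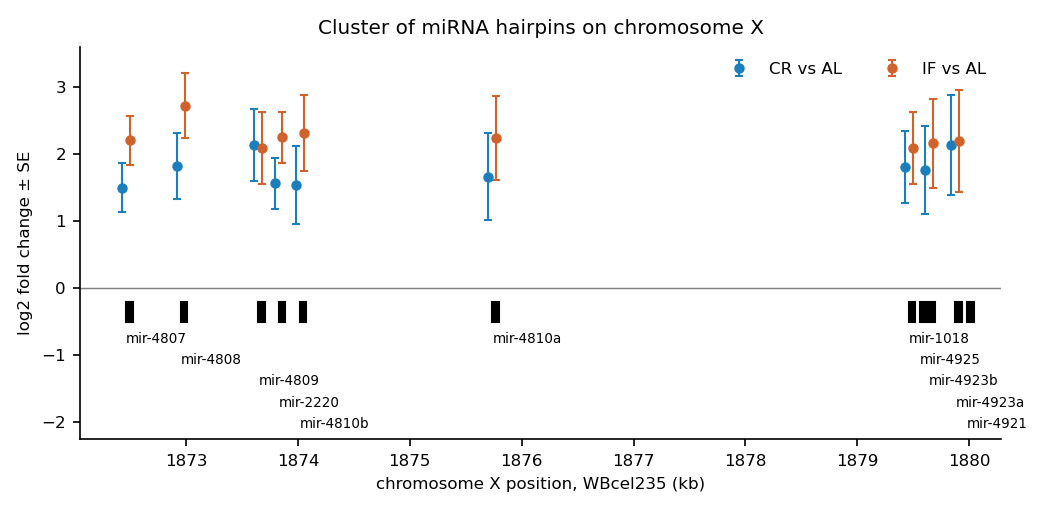
log2 fold change against AL (vertical axis, points with SE bars; n = 4 days) of the 9 tested arms of the chromosome X cluster in CR and IF, at the position of their hairpins in WBcel235 (horizontal axis, kb; black boxes are hairpins, and the 2 diets are set slightly apart). The region and the arms of mir-4809 and mir-4923a were chosen after their values were seen; all 9 arms lie above 0 in both diets.

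Among the lists fixed beforehand, the mir-58 family fell and the mir-35, mir-50 and mir-51 families rose in IF, each with a fry adjusted p of 0.0277. With an estimated correlation between members, camera, which sets a list against all other miRNAs, gave adjusted p = 0.494 for the mir-35, mir-51 and mir-58 families and adjusted p = 0.625 for the mir-50 family. The mir-58 family had all 4 tested members below 0 (median log2 fold change -1.16): miR-58a-3p and miR-82-3p passed over all miRNAs tested, and 4 of 4 when adjusted over the list alone. In the mir-35 family, which marks oocytes and embryos and is needed for embryonic development, 2 of 8 members rose, miR-37-3p and miR-39-3p (1.07 ± 0.33). Adjusted over the list alone, 4 of 8 passed, and miR-41-3p (-0.32 ± 0.37) had a value below 0. The mir-37 hairpin occupies positions 11537833 to 11537930 of chromosome II, opposite to an intron of Y62F5A.9, in a cluster of 7 family hairpins. In the mir-51 family 1 of 6 members rose, miR-51-5p (1.42 ± 0.37; chromosome IV, 11026013 to 11026112, intergenic), and 3 adjusted over the list alone. None of the 3 mir-50 family members passed on its own (0 adjusted over the list alone), with a median of 0.37 and 3 of 3 values above 0. Which lists passed depended on the scaling. With total counts, which shift all values upwards, fry passed 6: the median of the mir-58 family became -0.69 and the family no longer passed (fry adjusted p = 0.0631), while the mir-44 family (0.0132), the mir-2 family (0.0393) and the mirtrons (0.0393) did. With DESeq2's size factors the mir-44 family passed in addition to the 4 (fry adjusted p = 0.0240).

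**Figure D4:**
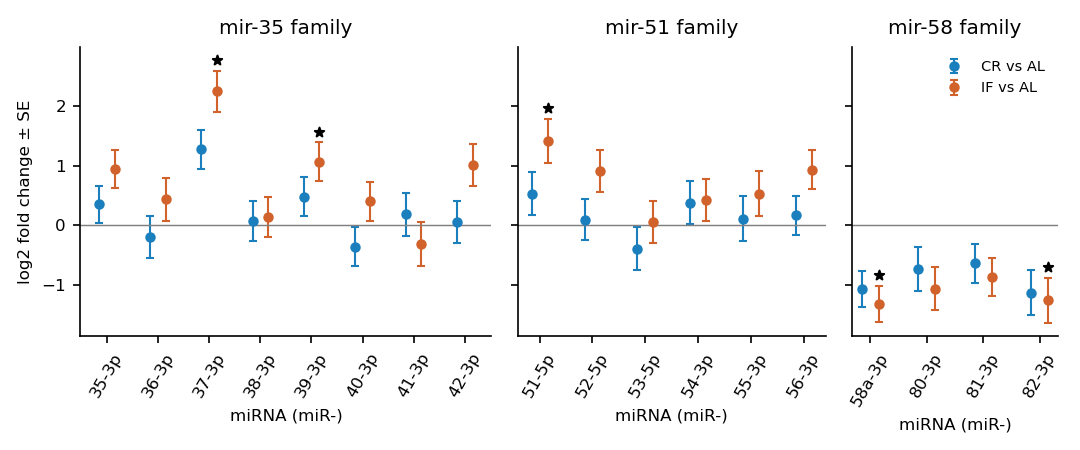
log2 fold change against AL (vertical axis, points with SE bars; n = 4 days) of each tested member of the mir-35, mir-51 and mir-58 families (horizontal axes) in CR and IF; stars mark an edgeR adjusted p under 0.05. All 4 mir-58 family values lie below 0 in both diets, and miR-37-3p, at 2.25 in IF, stands above the other mir-35 family members.

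The other lists did not pass in IF (fry adjusted p from 0.0630 for the mir-44 family to 0.915 for the mir-87 family), although single members did. In the let-7 family, 1 of 4 members fell, miR-48-5p, and 2 adjusted over the list alone; let-7-5p itself had a value of -0.89 ± 0.35. miR-797-5p was the 1 of 4 mir-2 family members that rose (1 adjusted over the list alone). In the mir-44 family 1 of 4 rose, miR-247-3p (1.95 ± 0.56, low), also 1 adjusted over the list alone; miR-44-3p and miR-45-3p count there as separate members although they share reads. Of 3 mirtrons, miR-1018 rose (2.10 ± 0.54, 1 adjusted over the list alone), and no protein-coding gene of the annotation used contains its hairpin. That hairpin belongs to the chromosome X cluster, so its rise is not separate from that of the cluster. Of 11 miRNAs with known lifespan phenotypes none passed (0 adjusted over the list alone), with miR-71-5p, which promotes long life, at -1.51 ± 0.66 and miR-228-5p at 0.88 ± 0.40. None passed in the mir-64 family (1 of 4 lower adjusted over the list alone), nor in the mir-72, mir-87 and mir-238 families or the pair lin-4-5p and miR-237-5p (0 adjusted over the list alone in each). Among tissue markers, the intestinal miR-60-3p fell (-1.06 ± 0.32, from 353.8 to 176.3 CPM, edgeR adjusted p = 0.0401, 1 of 4 adjusted over the list alone). Muscle miR-1-3p had -0.78 ± 0.49 and the neuronal miR-791-3p had 0.44 ± 0.47. For the neuronal mir-124, miR-124-5p was taken only because it had more reads. It was low and had an edgeR adjusted p of 0.114. The other arm, miR-124-3p, was low too (3.49 CPM in AL, 2.14 in IF).

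Without day as a block the IF against AL count was 0 of 212 by edgeR, with 17 at an unadjusted p under 0.05. It was 8 without the AL library of day 6, 17 without the IF library of day 6, 14 without the IF library of day 8, 6 without all day 6 libraries and 20 without all day 8 libraries, against 31; the count of lists fell from 4 to 0 without the AL library of day 4 or 6 or the IF library of day 4 or 8, and to 1 without the AL library of day 8 or all day 8 libraries.

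The second comparison asked the same of CR and AL. No single miRNA passed, and the values that came closest lay on the same side as in IF. The abundant miR-58a-3p averaged 258100 CPM in CR (SD 139800, n = 4 days) against 555800 in AL, a log2 difference of -1.08 ± 0.30, and miR-37-3p averaged 17800 CPM (SD 8110, n = 4 days) against 7078, a difference of 1.27 ± 0.33 (edgeR adjusted p = 0.0648 and 0.0610). Other small p-values belonged to miR-4807 (46.14 CPM in CR against 17.37 in AL), miR-2220-3p (1.57 ± 0.38), miR-49-3p (1.48 ± 0.39), miR-39-5p (-2.31 ± 0.60) and miR-41-5p (-1.22 ± 0.34), and to 3 low arms, miR-4809-3p (2.14 ± 0.54), miR-4808-3p (1.82 ± 0.50) and miR-8201-5p (-2.09 ± 0.56). edgeR's quasi-likelihood test passed 0 of 212 at an adjusted p under 0.05 (smallest 0.0610) and 39 at an unadjusted p under 0.05; limma-voom also passed 0 and DESeq2 passed 22, 12 higher and 10 lower. In simulated data of the same size, the test recovered 2 of 20 miRNAs changed 2-fold and 17 of 20 changed 4-fold.

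No list passed fry in CR. The mir-58 family came nearest, with 4 of 4 values below 0, a median of -0.91, fry adjusted p = 0.0687 and 2 of 4 members lower when adjusted over the list alone. camera with a preset correlation passed it (adjusted p = 0.00676), but not with an estimated correlation (adjusted p = 0.660). Adjusted over the list alone, miR-37-3p also passed in the mir-35 family (1 of 8) and miR-797-5p in the mir-2 family (1 of 4, 1.75 ± 0.54). So did miR-1018, of the chromosome X cluster, among the mirtrons (1 of 3, 1.81 ± 0.54). The lifespan, let-7 and remaining lists had none, and the marker miR-60-3p had -0.35 ± 0.31. The CR count was not stable at 0: edgeR passed 13 with total counts as the scaling, 8 with DESeq2's size factors, 9 without the CR library of day 8, and 6 without all libraries of day 4 or of day 8.

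CR and IF were then compared with each other, to ask whether the regimens differ. Values nearest to a difference were those of miR-37-3p (CR minus IF -0.98 ± 0.33), miR-77-3p (1.01 ± 0.35), miR-42-3p (-0.95 ± 0.36), muscle miR-1-3p (1.25 ± 0.52) and the low arms miR-70-5p (2.53 ± 0.68) and miR-1-5p (1.53 ± 0.49). The rest of the 10 with the smallest p-values were miR-4816-3p (-1.29 ± 0.46), miR-245-3p (1.03 ± 0.37), miR-79-5p (-1.08 ± 0.43) and miR-233-3p (-1.05 ± 0.44). edgeR passed 0 of 212 (smallest adjusted p = 0.475), 18 had an unadjusted p under 0.05, and DESeq2 and limma-voom passed 0 each. camera with a preset correlation placed the mir-35 family (adjusted p = 0.00819) and the mir-51 family (adjusted p = 0.00829) lower in CR than in IF, whereas fry gave adjusted p = 0.121 for each and camera with an estimated correlation adjusted p = 0.596 for each.

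Across the 212 miRNAs, which are not independent replicates, the fold changes of CR and IF against AL correlated with Pearson r = 0.81 (Spearman rho = 0.78), and 76.9% had the same sign. The AL libraries are common to both. In 100 simulations all 12 libraries, AL included, were redrawn without a diet effect. These gave r = 0.50 on average (at most 0.65) and 66.9% of equal sign. Each miRNA was drawn on its own there, so the simulated range of r can be too narrow where real miRNAs vary together. The covariance was 0.604, against 0.113 in the simulations, a difference of 0.491. With CR and IF set against different AL days, r averaged 0.48 (0.23 to 0.73 over the 6 ways to divide the days) and the covariance 0.464. miR-58a-3p, miR-37-3p and miR-49-3p are among those that lay on the same side of AL on 4 of 4 days in both diets.

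The time course asked which miRNAs change with adult age, with a slope common to the diets. The fitted slopes of miR-63-3p, miR-64-5p, miR-65-5p, miR-238-3p and miR-83-3p lay above 0 and those of miR-34-5p, miR-36-3p and let-7-5p below it, though single days departed from these lines. miR-63-3p (chromosome X, 17598765 to 17598868) rose by 0.70 ± 0.10 log2 units per day (edgeR adjusted p = 0.000736), in AL from 448.1 CPM on day 2 to 12030 on day 10. miR-64-5p rose by 0.87 ± 0.17 and miR-65-5p by 0.56 ± 0.11 per day (adjusted p = 0.00362 each by edgeR); their hairpins are neighbours in an intron of gcn-1, between 2172848 and 2173101 on chromosome III. miR-34-5p, whose relatives act downstream of p53 in mammals, changed by -0.50 ± 0.12 per day, in AL from 1624 CPM on day 2 to 202.7 on day 10. In all, 32 of 215 tested miRNAs passed edgeR's quasi-likelihood test, 15 rising and 17 falling, with 64 at an unadjusted p under 0.05. These errors treat libraries of the same day as independent, although they moved together. With day as a random block, a choice made after seeing the data, limma-voom passed 4, against 29 without it: miR-63-3p rose, and miR-79-5p, miR-36-3p and miR-38-5p fell (limma adjusted p from 0.00392 to 0.0307). miR-64-5p, at 0.86 per day (limma adjusted p = 0.0529), and miR-34-5p, at -0.44 (limma adjusted p = 0.0931), no longer passed.

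The largest rises besides those were of miR-239b-3p (0.95 ± 0.17), miR-47-5p (0.47 ± 0.14), miR-786-3p (0.46 ± 0.10), miR-357-3p (0.44 ± 0.12) and the low miR-4808-3p (0.61 ± 0.12). The largest falls were of miR-38-5p (-1.01 ± 0.15), miR-36-3p (-0.89 ± 0.16), miR-79-5p (-0.86 ± 0.13), miR-37-5p (-0.75 ± 0.16), miR-42-5p (-0.62 ± 0.11), miR-34-5p, miR-232-3p (-0.49 ± 0.12), miR-2-5p (-0.46 ± 0.14), miR-243-5p (-0.44 ± 0.14) and the low miR-49-5p (-0.57 ± 0.16). miR-38-5p, miR-37-5p and miR-42-5p are the less abundant arms of mir-35 family hairpins.

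**Figure D5:**
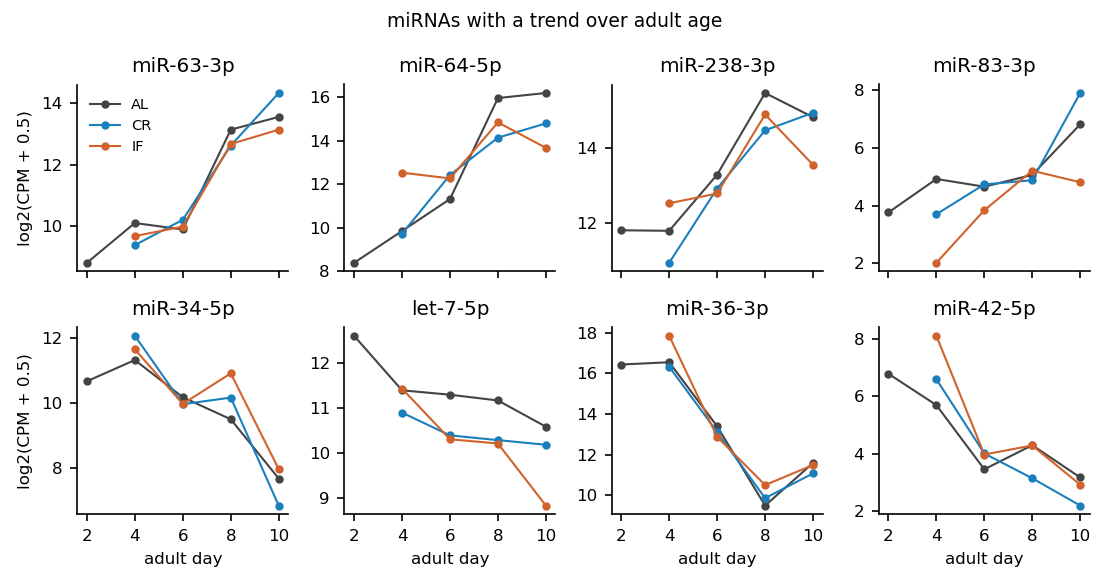
log2(CPM + 0.5) (vertical axes, each with its own range) of 8 miRNAs past edgeR's test for age, on each adult day (horizontal axes). Each point is 1 library and lines join the libraries of a diet. Of the 8, only miR-63-3p and miR-36-3p also passed limma-voom with day as a random block. The fitted slopes of miR-63-3p, miR-64-5p, miR-238-3p and miR-83-3p lie above 0, and those of miR-34-5p, let-7-5p, miR-36-3p and miR-42-5p below it.

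Of the 11 lifespan miRNAs, miR-83-3p (0.46 ± 0.10) and miR-238-3p (0.51 ± 0.12) rose and miR-34-5p fell; adjusted over the list alone, 3 rose and 2 fell. As a list they did not move in 1 direction (fry adjusted p = 0.203). Of the list members named in this paragraph, only miR-36-3p also passed with day as a random block; miR-83-3p, miR-238-3p and miR-34-5p had limma adjusted p of 0.284, 0.0931 and 0.0931. The mir-64 family had 2 of 4 members rising (2 adjusted over the list alone; fry adjusted p = 0.113) and the mir-238 family 1 of 3, the same miR-238-3p (1 up and 1 down adjusted over the list alone). In the mir-35 family 1 of 8 fell, miR-36-3p (1 adjusted over the list alone; fry adjusted p = 0.120). In AL, miR-36-3p went from 88810 CPM on day 2 to 713.5 on day 8 and 3070 on day 10. In the let-7 family 1 of 4 fell, let-7-5p (-0.23 ± 0.07; 1 up and 1 down adjusted over the list alone), and in the mir-2 family 1 of 4 rose, miR-43-3p (0.35 ± 0.11; 1 adjusted over the list alone). Members that passed only when adjusted over the list alone had slopes above 0 in the mir-44 (3 of 4, of which 2 share their reads), mir-50 (2 of 3) and mir-72 (2 of 3) families and among mirtrons (1 of 3). Without the day 8 libraries, a choice made after seeing the data, the slope of miR-44-3p went from 0.87 to 0.07 per day and that of miR-90-3p from 0.73 to 0.02. Those of miR-62 (1.18 to 0.50), miR-72-5p (0.47 to 0.33) and miR-74-3p (0.44 to 0.28) became smaller but passed over all miRNAs (edgeR adjusted p = 0.00192, 0.0188 and 0.0384). So did that of miR-48-5p of the let-7 family (0.81 to 0.25, edgeR adjusted p = 0.0164). The mir-51, mir-58 and mir-87 families and the lin-4 pair had 0 by either adjustment. The neuronal marker miR-791-3p rose (0.32 ± 0.10), while miR-1-3p (0.49 ± 0.23), miR-60-3p (0.20 ± 0.10) and miR-124-5p (low; 0.19 ± 0.08) did not pass.

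fry passed 0 of 13 lists for age (5 at an unadjusted p under 0.05; 0 by camera with either correlation), and 6 once the day 8 libraries were left out, a choice made after seeing the data. The count of 32 miRNAs became 19 without the AL library of day 4, 20 without that of day 10, 19 and 20 without the CR libraries of day 4 and day 6, 18 without the IF library of day 4, 17 with total counts as the scaling, 20 with total counts that leave out the top 3 miRNAs, 19 with the logarithm of day and 65 by DESeq2.

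Within each diet the trend rested on few libraries. In AL, miR-64-5p rose by 1.13 ± 0.21 log2 units per day (edgeR adjusted p = 0.0407), the 1 of 215 that passed; 36 had an unadjusted p under 0.05, DESeq2 passed 23 and limma-voom 4. It no longer passed without the AL library of day 2, 4, 6 or 10, the CR library of day 4, 6 or 8, or the IF library of day 4 or 6 (0 in each case). In CR edgeR passed 0 (22 at an unadjusted p under 0.05; DESeq2 14, limma-voom 1) and in IF 0 (20 at an unadjusted p under 0.05; DESeq2 18, limma-voom 0). For slopes that differ between the diets edgeR passed 0 of 212, as did DESeq2 and limma-voom; the 1 with an unadjusted p under 0.05 was miR-67-3p, with slope differences from AL of 0.11 per day in CR and 0.63 in IF. For miR-64-5p the differences were -0.40 in CR and -0.90 in IF, with an edgeR adjusted p of 0.999. In simulated data this test recovered 0 of 20 miRNAs whose slopes differed 16-fold over 6 days, so a count of 0 sets no limit on such differences.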

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

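The tests of library size, hairpin arms and batches in this part were chosen after the result was seen, as was the condition that a test of neighbours or arms must work for a diet comparison, and that of neighbours also between other days, before it is read; that condition made both readings open.

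In 20 of 276 groups of 4 or 5 libraries, 1 library stood apart from the others of its diet, by a gap that is a large part of the whole range of the values. Chance gives this in about 5% of groups, or 13.8 of 276. The groups cover 3 diets, with log2 CPM of 88 named miRNAs of a mean CPM of 10 or more and 4 measures of the libraries, none of which stood apart; a first list of fewer miRNAs was widened to these after its result was seen. Of the 20, 11 were on day 8, against 3 on day 4, 2 on day 6 and 4 on day 10. On day 8, miR-90-3p in AL (25560 CPM, others 450.1 to 1066), miR-44-3p in IF and miR-45-3p in IF (121700 CPM each, others 1584 to 3162) were highest, with a gap of 0.787, 0.841 and 0.841 of the range; the last 2 share their reads, so they are 1 finding counted as 2. Also highest on day 8 were miR-237-5p in CR (0.839), miR-4807 in IF (0.873), miR-791-3p in IF (0.866), miR-4810b-3p in AL (0.943) and miR-73-5p in AL (0.722). Lowest on that day were miR-4810a in IF (0.882), miR-52-5p in AL (0.796) and miR-87-3p in AL (0.765).

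On the other days, the highest were miR-2-3p (0.951), miR-239b-3p (0.909) and miR-357-3p (0.85) in IF on day 10, miR-239b-3p in AL on day 10 (0.749), miR-46-3p in IF on day 6 (0.84) and miR-239b-5p in CR on day 4 (0.875). The lowest were miR-1018 (0.837) and miR-228-5p (0.901) in IF on day 4 and miR-229-5p in AL on day 6 (0.818). miR-239b-3p, which rose with age, had 54.06 CPM on day 10 in AL and 0.2381 to 1.677 on the other days. The low miR-1-5p (mean CPM 2.69) lay above AL in CR on 4 of 4 days (mean log2 ratio 0.57) and below it in IF on 4 of 4 days (-0.75), a difference of 1.32; the test of CR against IF gave it an edgeR adjusted p of 0.496.

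The day 8 libraries differed from those of the other days in all 3 diets and in the same miRNAs. Deviations of day 8 from the neighbouring days correlated between diets with r of 0.866 to 0.901 across miRNAs. miR-44-3p deviated by 5.91 log2 units, miR-62 by 5.74, miR-90-3p by 4.59 and miR-48-5p by 4.17. miR-42-3p, from the same cluster as mir-44, deviated by -2.69. As miR-44-3p shares its reads with miR-45-3p, its deviation cannot be assigned to the mir-44 hairpin alone. The tables argue against library size, since 3 of 3 day 8 totals lie inside the range of the other 10. A few miRNAs taking most of the counts would shift the rest alike. The log2 ratios of pairs with day 8 had an SD of at least 1.97 over miRNAs, against at most 1.90 for pairs without it. The margin is small and this SD includes those few miRNAs themselves, so it does not decide on this cause. Uneven capture of sequences during library preparation stays open: the day 8 deviations of neighbouring hairpins of different families differed by 2.80 on average, no less than random pairs (2.06; permutation p = 0.963), but neighbours were no closer for day 10 minus day 6 either (1.51 against 1.66; permutation p = 0.328). They were closer for day 6 minus day 4 (0.767 against 1.145; permutation p = 0.0280) and IF against AL (0.347 against 1.145; permutation p = 1e-04, the smallest 10000 draws can give), but 34 of the 52 pairs lie in the chromosome X cluster, which was picked for its IF values, and without it these gave permutation p = 0.0533 and 0.00390. The arms of a hairpin differed by 2.22 against 2.17 for random pairs (permutation p = 0.606), but arms were no closer for IF against AL either (permutation p = 0.314), so this test decides nothing; a batch cannot be told apart from a change in the animals at this age, as the labels name 0 batches and each day was sampled once.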

How the results depend on the processing

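Tests of other groupings of the libraries for CR against AL, CR against IF and diet by age, the exchange of whole days for age, how all these tests are read, and the settings without day 8, without miR-45-3p or with day as a random block were chosen after the result was seen. The IF against AL count of 31 depended most on the day block: it was 0 with no replicate block and 0 with day as a number, 17 with only the 2 diets, 52 by DESeq2, and 6 (without all day 6 libraries) to 34 (without the IF library of day 10) with libraries or days left out. The lists passing were 4 by fry, 1 by camera with a preset correlation, 0 with an estimated one, 0 with no replicate block, 6 with total counts, 5 with DESeq2 size factors, 1 without day 8, and 0 to 5 with single libraries left out; the counts of the other diet comparisons, 0 with the block, were 0 without it as well. The CR against AL count of 0 became 16 at an adjusted p under 0.10, 8 with DESeq2 size factors, 13 with total counts (13 higher, 0 lower), 2 with total counts without the top 3, 22 by DESeq2, 22 with no low-count filter, 8 with 100 reads in 4 libraries, 5 with only the 2 diets and 9 without miR-45-3p, and was 0 to 9 with libraries left out (9 without the CR library of day 8). Its lists became 1 by camera with a preset correlation, 4 with total counts and 1 with DESeq2 size factors. For CR against IF the count stayed 0 in the alternatives run, while its lists became 2 by camera with a preset correlation and 0 to 1 with libraries left out (1 without the CR library of day 6).

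The age count of 32 became 17 with total counts, 20 with total counts without the top 3, 65 by DESeq2, 4 by limma-voom with day as a random block, 19 with log2 of day, and 18 (without the IF library of day 4) to 31 with libraries left out; lists became 3 with total counts and 6 without day 8. The AL slope count of 1 became 3 at an adjusted p under 0.10, 2 with DESeq2 size factors, 23 by DESeq2, 4 by limma-voom, 0 without AL day 2, 2 with log2 of day, 3 without day 8, and 0 to 2 with libraries left out. The CR slope count of 0 became 14 by DESeq2, 1 by limma-voom and 7 without day 8, and the IF slope count of 0 became 18 by DESeq2. The correlation of CR and IF fold changes became 0.48 with the AL days split, and was 0.66 to 0.85 with a day left out. The diet share of variance was 11.4% to 20.1% and the day share 61.9% to 79.3% over those settings. With diets exchanged, the average diet share also varied over them, from 6.27% to 12.7%. The causes were not tested, except that fewer libraries leave fewer degrees of freedom.

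Among named miRNAs past the threshold no direction reversed: 48 of 48 kept their call by DESeq2, 45 with DESeq2 size factors, 44 by limma-voom, 41 with total counts without the top 3, 34 with total counts, 371 of 521 over libraries left out, and 0 of 25 with no replicate block. Under total counts, where the median of all miRNAs shifted by 0.418 in CR and 0.458 in IF, the medians of the lifespan list, the mir-87 family and the lin-4 pair changed sign in both diets, those of the let-7 and mir-64 families in CR and those of the mir-238 family and the tissue markers in IF. For IF against AL the real split gave the most calls (31 against at most 9; 1 of 35 as large) and lists (4 against at most 2; 1 of 35). Only 8 of the 35 part all 4 days as the real one does, the others of these gave at most 0, and 8 are too few for a share under 0.05. For age, 3 of 100 exchanges of days within each diet gave as many as 32 (at most 53), but these break up the days that libraries share. With days 4 to 10 exchanged together in all diets, 6 of 24 orders gave as many, so chance cannot be excluded. The highest, 74, had days 8 and 10 exchanged, and the reason was not tested. For CR against AL (0, others up to 9, at most 1 where all days are parted; 35 of 35 as large), CR against IF (0, others up to 4; 35 of 35) and diet by age (0, others 0; 100 of 100) the test decides nothing, as every split reaches 0. Depth limits low arms most: 3 reads are worth up to 1.137 CPM.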

Other observations

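The tests of scaling, low counts and diet control in the chromosome X cluster, of oocytes in the mir-35 family and of passenger arms were chosen after the result was seen; the rules for diet control and for oocytes were tightened after their values were known.

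Other miRNAs past the threshold, chosen after their values were seen, included miR-254-3p (1.68 ± 0.39), miR-4816-3p (1.65 ± 0.46), miR-796 (1.46 ± 0.42) and miR-72-3p (1.10 ± 0.35), higher in IF than in AL, and miR-47-3p (-1.13 ± 0.35), lower (n = 4 days each; edgeR adjusted p from 0.0105 to 0.0478). With age, miR-86-5p (0.36 ± 0.07 per day), miR-49-3p (0.35 ± 0.09) and miR-4937 (0.29 ± 0.09) rose and miR-793 (-0.42 ± 0.09), miR-229-3p (-0.42 ± 0.12) and miR-250-5p (-0.36 ± 0.10) fell by edgeR, but none of these 6 passed with day as a random block (limma adjusted p from 0.0810 to 0.439). miR-229-3p, the less abundant arm of its hairpin, fell while the more abundant arms miR-64-5p and miR-65-5p of the same cluster rose. This sets unlike arms against each other. The more abundant miR-229-5p had a slope of -0.006 per day (edgeR adjusted p = 0.960). The less abundant miR-64-3p and miR-65-3p had slopes of 0.16 and -0.07 (edgeR adjusted p = 0.712 and 0.851). The mir-254 hairpin lies within gcy-9, mir-4816 within T09B4.2 and mir-229 within gcn-1.

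The chromosome X cluster has 11 hairpins starting at 1872466, and its 9 tested arms had a mean log2 fold change of 2.25 in IF (SD 0.19) and 1.77 in CR (SD 0.24), 9 of 9 above 0 in each. CR minus IF averaged -0.48 (SD 0.329), and no arm passed edgeR's test of that difference. The tables argue against the choice of scaling (lowest mean over the scalings 2.22) and members holding wholly the same reads. Of pairs with different name numbers, 34 of 34 differed beyond counting noise, as did the 2 pairs with the same number, of mir-4810 and mir-4923. A few low counts are argued against only in part. Over all libraries 6 members past the threshold had a mean CPM of 10 or more, but high values in CR and IF lift that mean. In AL, miR-1018 (50.86 CPM), miR-4807 (17.37) and miR-2220-3p (14.47) averaged over 10. The other arms averaged 1.13 (low miR-4809-3p) to 6.45 (miR-4923b) there, so low AL counts stay open for them. Reads shared in part were not tested. Control of the whole cluster by diet stays open. In IF 9 of 9 arms lie above 0, but the cluster was picked for its values. In CR none of its arms passed over all miRNAs tested, though the mean exceeded the highest of 10000 random sets of similar abundance (0.815). CR and IF are set against the same AL libraries, so CR is not a separate test.

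Within the mir-35 family the IF members were unequal: mean log2 ratios to AL over 4 days were 2.22 for miR-37-3p, 1.05 for miR-39-3p, 0.97 for miR-42-3p, 0.95 for miR-35-3p, 0.40 for miR-36-3p, 0.37 for miR-40-3p, 0.13 for miR-38-3p and -0.37 for miR-41-3p. Their spread (SD 0.777) exceeded that of exchanged member labels (permutation p = 1e-04, the smallest possible). More oocytes or embryos in IF stay open as a cause, since the members kept no fixed profile: between AL days their log2 ratios had an SD of 0.662 to 2.14, against 0.584 to 1.201 for IF against AL on a day. The values argue against members holding wholly the same reads (7 of 7 differed from miR-37-3p beyond counting noise). miR-37-3p exceeded the median of the others by 1.81 to 1.83 over the scalings. Scaling shifts all members of a library alike, so this outcome was fixed in advance and tests nothing. Reads split in part between members, and unequal control of members, were not tested.

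Among the 7 mir-35 family hairpins with both arms tested, 4 passenger arms and 0 guide arms fell with age past the threshold by edgeR, of which only miR-38-5p also passed with day as a random block; miR-36-3p, which fell, is a guide arm whose partner was not tested. The family's mean slope difference, passenger minus guide, was -0.298 per day (SD 0.481, 7 hairpins), against -0.158 for the other hairpins, at percentile 23.3 of 10000 random sets.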
